A study of Mus musculus with 2 samples.

How the data were processed

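Messenger RNA of NIH3T3 cells, an established mouse fibroblast line, was measured in 1 untreated library and in 1 library of cells kept with 100 µM ALA for 16 h. Per the labels' protocols, libraries were made with the TruSeq RNA kit and read as single-end reads of 41 bp on a Genome Analyzer IIx. The deposited values are FPKM per gene, in a tracking table of the layout that Cufflinks writes, per the file headers. Reads were checked with FastQC 0.11.5, aligned with TopHat2 2.1.1 and quantified with Cufflinks 2.2.1 on mouse build mm10, per the submitters' processing notes, where only the tool names, versions and build are given and their roles are those usual for these tools. The annotation, the options and the scaling between libraries are not given in the sources used here. No strand setting is given either, so reads of genes that overlap on opposite strands are treated as not separable.

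The table held 22838 genes, with 1 FPKM value per library. The deposited lower and upper interval bounds were equal in 100% of the rows and therefore carried no error. The status was FAIL for 1 gene, Bclaf1 in the untreated library. FPKM values are not counts, so no count model was used. All comparisons were made on the scale log2((ALA FPKM + 1)/(untreated FPKM + 1)), which understates the ratio of low genes, while a fold is the plain ratio of the FPKM values. Genes with a mean FPKM of at least 1 over both libraries, 10929 in number, entered the counts and the gene lists, and such genes are called measured. Counts of members at least 1.5-fold or 2-fold apart, and of genes 8-fold apart unless said otherwise, use the log2 scale with the added 1.

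Before the data were examined, 29 gene lists, the named genes, the thresholds and most alternatives were fixed. For each list with at least 3 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean FPKM. A list is said to stand apart below percentile 2.5 or above percentile 97.5. The percentile is given as a description of these libraries and is no test of the treatment. The named genes were Srrd, all members of the lists for heme synthesis, heme breakdown and the core clock, the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 5 FPKM, status OK, 1 gene name and no small-RNA name, and up to 4 members with the largest log2 ratios of every other list. For marker lists of other cell types the member with the highest FPKM was added. Some genes that this rule names are not reported here. Other genes in the text were named after their values were seen, as illustration of a list.

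Depth was estimated from the steps between low values, taking an FPKM value times transcript length as roughly a whole multiple of what 1 read is worth. For 461 genes with values between 0.001 and 0.1 FPKM in both libraries, 35.6% of the ratios of ALA to untreated lay within 0.06 log2 of a ratio of small whole numbers, after scaling by the best relative depth, against 14.8% at other scalings. The step itself, fitted on genes with a single transcript of over 1500 bp, gave 23800000 reads for the untreated library, with 21000000 to 24300000 giving nearly as good a fit, and 32200000 for the ALA library. The ratio of the depths was 1.35, and 95.5% of 200 bootstrap resamples fell within 0.05 log2 of it. Approximate reads per gene were the FPKM times the length of the longest transcript times this depth, and approximate 95% counting intervals of the log2 ratio were computed from them. These intervals cover counting error only, and rest on this estimate of depth. They are narrower than the spread between genes: with a mean of 1 to 5 FPKM, the middle 95% of log2 ratios ran from -1.29 to 1.19.

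Gene positions came from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names. Of the deposited genes, 22310 (97.7%) matched a gene model at the same position. The share of the 41-base stretches of each gene that also occur in another gene, and the share of its exon bases inside another gene of the table, were computed from that annotation. Only exact matches to annotated transcripts of other genes were counted, so a low share does not exclude reads that align elsewhere with mismatches. Members of the mitochondrial DNA-encoded list, and Flvcr1, Flvcr2, Hbb-bt and Ahsp, had no matching entry and were not analysed here.

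The procedure was tested on simulated counts for 22310 genes at these depths. With no change, 10 runs gave on average 0.1 genes at 2-fold or more among measured genes. Of 50 genes per size, all drawn from genes with a mean of at least 5 FPKM, 96.0% were recovered at 2.5-fold. At 3-fold, 4-fold and 6-fold 100.0% were recovered. Recovery was not simulated for measured genes with a lower mean, whose log2 ratios the added 1 shrinks more. Of 400 lists without change 4.8% stood apart, and a planted list raised 1.5-fold reached percentile 100.0. The lists without change were random draws from the same genes as the reference lists, so their share was set by the percentile limits. It does not show how often lists of co-regulated genes stand apart. These simulations hold counting noise and no variation between cultures. The list checks also hold random noise added to each log2 ratio, drawn independently for each gene.

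The alternatives were pseudocounts of 0.1 and 5, ALA values rescaled to a median ratio of 1, equal totals without the 50 highest genes, no filter, a mean of at least 5 FPKM, status OK genes, no small-RNA names, thresholds of 1.5-fold and 3-fold, 10 expression bins, the mean of members and lists without each member. A filter on shared sequence under 10% and a correction for GC content and transcript length in 10 by 10 bins, and a count of 8-fold ratios of plain FPKM, were added after the data were seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.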

Results

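Gene expression was profiled by mRNA sequencing in NIH3T3 mouse fibroblasts, in 1 untreated library and 1 library of cells exposed to 100 µM ALA for 16 h. The labels give only the abbreviation ALA, which in work on heme stands for δ-aminolevulinic acid, the committed precursor of heme. The title of the series is about SRRD, heme synthesis and circadian rhythms, so the comparison asks which transcripts differ between cells with and without ALA. Estimated depth was 23800000 reads in the untreated library and 32200000 in the ALA library. The deposited FPKM values summed to 540963 and 512324, and 10894 and 10888 genes reached 1 FPKM.

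With ALA, Srrd was 4.63-fold higher and Hmox1, which encodes the inducible heme oxygenase, was 2.09-fold higher. Alas1, the gene of the first and rate-limiting enzyme of heme synthesis outside erythroid cells, was 2.25-fold lower. All 17 genes of the hypoxia and glycolysis list were lower, with a median log2 ratio of -1.04. Lists of antioxidant and cell division genes were modestly higher, and lists of immediate early and inflammatory genes were lower. Porphyrin transport and heme breakdown genes (higher) and metallothionein and macrophage marker genes (lower) also stood apart, but lost that call under other settings or without single members. Among 10929 measured genes, 163 were at least 2-fold higher and 220 at least 2-fold lower in the ALA library, together 3.5%. The counts were 302 and 389 with a pseudocount of 0.1 and 31 and 42 with 5, and equal library totals gave 187 higher and 173 lower, so the excess of lower genes depends on the scaling. Across genes, which are not independent replicates, the libraries correlated with a Pearson r of 0.968 and a Spearman rho of 0.967, and the median log2 ratio was -0.019. With 1 library per group no difference has a replicate check and no p-value is given. Counting noise alone gave on average 0.1 genes at 2-fold in simulation, which does not cover variation between cultures.

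**Figure D1:**
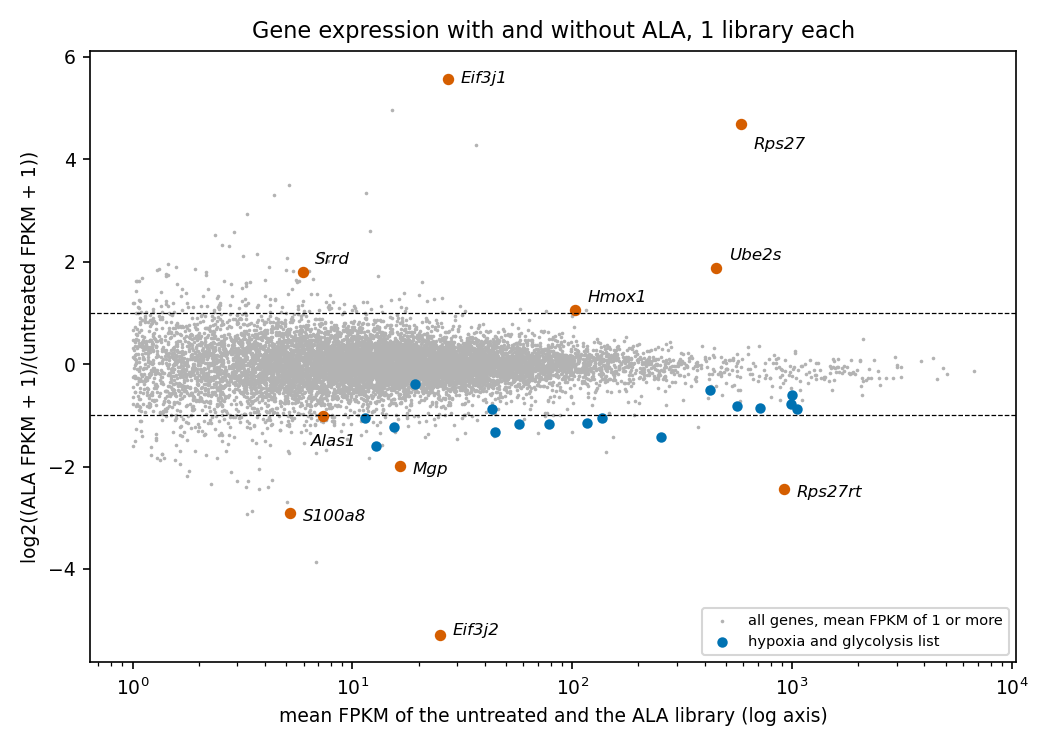
Each grey point is a gene with a mean of at least 1 FPKM, with mean FPKM on a log axis and the log2 ratio of ALA to untreated on the vertical axis; dashed lines mark 2-fold, blue points the hypoxia and glycolysis list and orange points labelled genes. Srrd lies at 1.79 and Alas1 at -1.02, and all 17 blue points lie below 0.

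Srrd, the gene of the series title, had 2.11 FPKM in the untreated library and 9.76 FPKM in the ALA library. These values correspond to about 56 and 349 reads, and the log2 ratio was 1.79 with an approximate 95% counting interval of 1.5 to 2.08. Srrd ranked 14 from the highest among the 8607 genes with a mean of at least 5 FPKM. In the GENCODE annotation of GRCm38 the gene lies on the minus strand of chromosome 5, from 112337392 to 112343040, and its longest transcript has 1110 bp in 7 exons. Its 3' end overlaps the 3' end of Tfip11, a splicing factor gene on the plus strand at 112326358 to 112338073, over 515 exon bases or 31.4% of the Srrd exon sequence. Tfip11 had 11.98 FPKM untreated and 14.2 FPKM with ALA, a log2 ratio of 0.23. The neighbour Hps4, which shares no exon bases with Srrd, had 5.53 and 4.41 FPKM. Because no strand setting is given, reads in the shared exon sequence cannot be assigned to Srrd or Tfip11 with certainty.

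In the heme synthesis list, 6 of 8 measured genes were higher and 2 lower in the ALA library, with Alas1 the only member at 2-fold. Alas1 had 10.2 FPKM untreated and 4.52 FPKM with ALA, a log2 ratio of -1.02 with a counting interval of -1.16 to -0.88. Equal library totals shift log2 ratios upward by about 0.07, so the 2-fold call of Alas1 depends on the scaling. Uros, the uroporphyrinogen III synthase gene, went from 3.20 to 5.84 FPKM (log2 ratio 0.70), and Ppox, the protoporphyrinogen oxidase gene, from 1.34 to 3.24 FPKM (0.86). Ppox shares 17.5% of its exon bases with B4galt3, so its value is uncertain. The log2 ratios of Cpox, Fech and Urod were 0.21, 0.16 and 0.08, and that of Alad was -0.05, a sign that turned to 0.01 with equal library totals. Alas2, the erythroid counterpart of Alas1, was listed at 0 in both libraries. The list median of 0.18 was at percentile 92.04 of random lists and did not stand apart.

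Heme breakdown genes were higher in 3 of 4 cases. Hmox1 went from 66.8 to 139 FPKM, a log2 ratio of 1.05 with a counting interval of 0.99 to 1.12. Blvra, which encodes biliverdin reductase A, had a log2 ratio of 0.44, Hmox2 of 0.13 and Blvrb of -0.10. Hmox2 shares 43.8% of its sequence with other genes, of which Cdip1 shares the most. The list median of 0.28 was at percentile 98.41. It was 0.13 without Blvra, at percentile 81.08, and likewise without Hmox1, at percentile 81.00, so the call needs both genes. The mean of the members was 0.38, at percentile 99.53.

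**Figure D2:**
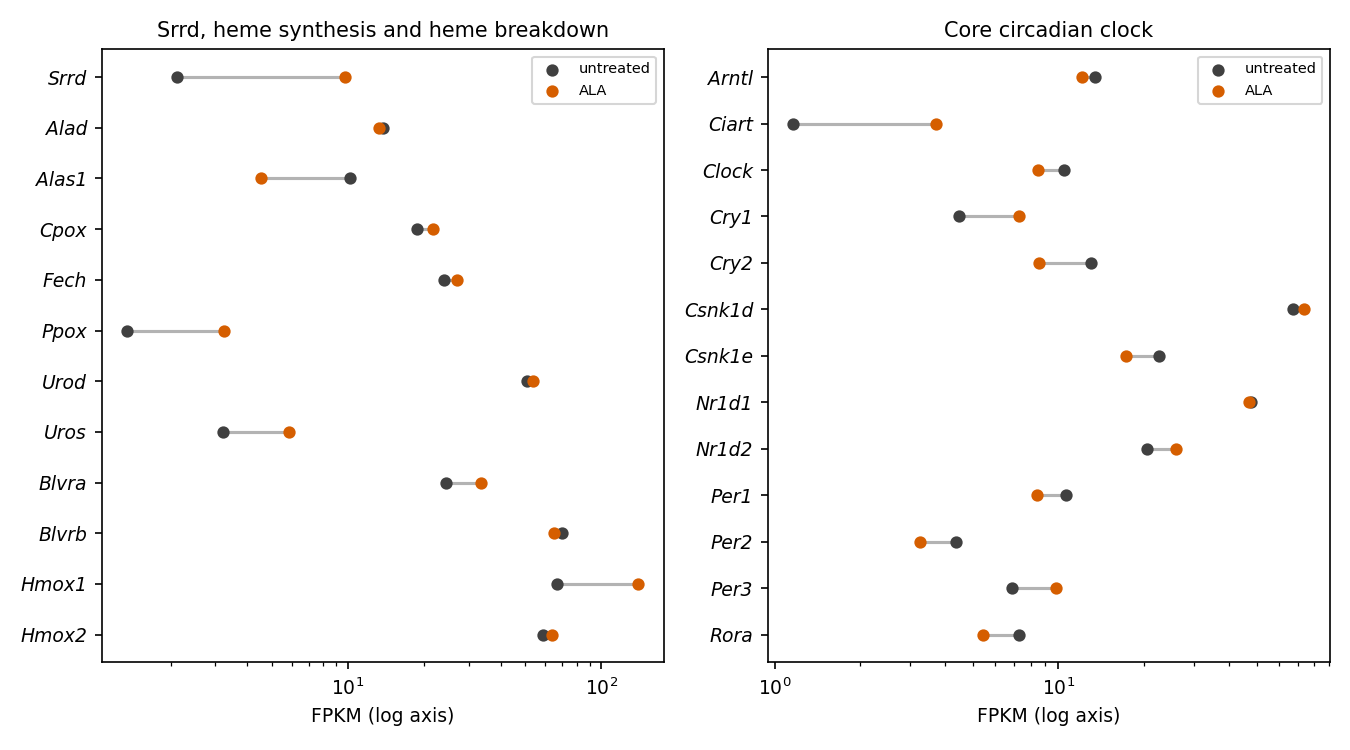
FPKM on a log axis in the untreated library (grey) and the ALA library (orange), 1 library each, for Srrd with heme synthesis and breakdown genes (left) and for core clock genes (right), drawn where named in the text and with a mean of at least 1 FPKM. Srrd moves from 2.11 to 9.76 FPKM and Hmox1 from 66.8 to 139 FPKM, while Nr1d1 stays at 47.6 and 46.9 FPKM.

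Genes for porphyrin, heme and ALA transport had a median log2 ratio of 0.36, at percentile 99.98. Of 13 measured members 7 were higher and 6 lower. Slc25a38, the mitochondrial glycine carrier that feeds heme synthesis, had a log2 ratio of 0.61, Tmem14c, a mitochondrial protoporphyrinogen transporter, 0.60, and Hebp1, a heme-binding protein, 0.51. The peptide transporter gene Slc15a2 was lower at -0.67, from 1.55 to 0.60 FPKM. Leaving out any 1 of the 7 higher members ended the call, as without the porphyrin transporter gene Abcb6, when the median was 0.17 at percentile 97.11. The mean of the members was 0.14, at percentile 92.12.

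The NRF2 and BACH1 antioxidant list stood apart with a median of 0.14 at percentile 99.77, with 13 of 20 genes higher. Gclm, a subunit of the enzyme that starts glutathione synthesis, had a log2 ratio of 0.66, thioredoxin reductase Txnrd1 0.56, sulfiredoxin Srxn1 0.48 and the glutathione transferase Gsta4 0.35. Iron genes had a median of 0.06 at percentile 86.20 and did not stand apart. Within that list the iron exporter Slc40a1 was higher at 0.82 and the transferrin receptor Tfrc at 0.75, while the mitochondrial iron importer Slc25a37 was at -0.56 and the ferritin receptor Ncoa4, with 18.2% shared sequence, at -0.55. The respiratory chain list with heme A synthesis had a median of 0.06 at percentile 85.00. Its members went both ways: Cox10, which acts first in heme A synthesis, was at 0.88 and Cox15, which acts after it, at -0.54. Sdhc and Uqcrc2 were at 0.39 and 0.30, and Uqcrc2 shares 18.1% of its sequence.

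Hypoxia and glycolysis genes had the lowest median of the 24 fixed lists with enough members, at -1.04 and percentile 0.00. All 17 members were lower in the ALA library, 15 of them at least 1.5-fold and 9 at least 2-fold. The mitophagy receptor gene Bnip3 went from 371 to 138 FPKM (log2 ratio -1.42), pyruvate dehydrogenase kinase Pdk1 from 64.0 to 25.03 FPKM (-1.32), and hexokinase Hk2 from 22.1 to 8.85 FPKM (-1.23). Ankrd37 had the lowest ratio of the list, -1.59, but 26.4% of its exon bases lie in other genes. Bnip3 shares 51.7% of its sequence with other loci. The abundant glycolytic genes Gapdh, Pgk1 and Aldoa went from 1249 to 727, from 1366 to 747 and from 916 to 506 FPKM. Gapdh and Pgk1 share 26.5% and 54.3% of their sequence with other loci, and Aldoa 10.1%. The smallest differences were those of Eno1 at -0.50 and Vegfa at -0.39.

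**Figure D3:**
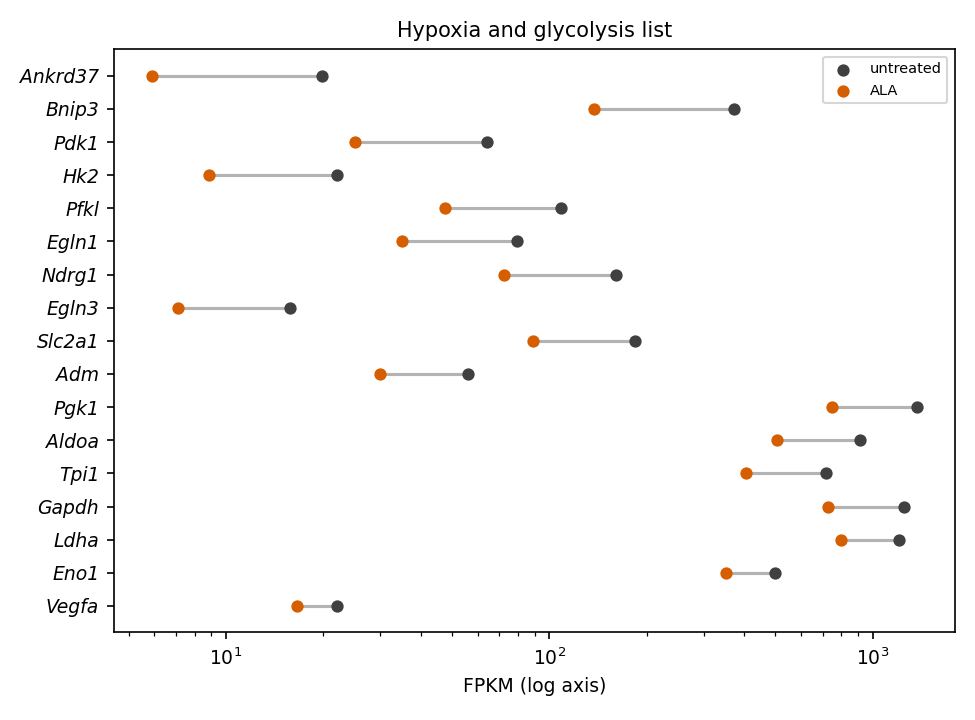
FPKM on a log axis of the 17 hypoxia and glycolysis genes in the untreated (grey) and ALA (orange) library, 1 library each, sorted by log2 ratio. Every orange point lies left of its grey point, from Ankrd37 at -1.59 to Vegfa at -0.39.

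Core clock genes did not move in a common direction. Of 14 measured members, 5 were higher and 9 lower in the ALA library, and the median of -0.17 was at percentile 6.92, within the range of random lists. Ciart, a repressor of CLOCK and BMAL1 activity, went from 1.16 to 3.72 FPKM (log2 ratio 1.12, counting interval 0.87 to 1.38). Ciart shares 15.9% of its sequence with other genes, of which Gm9176 shares the most. Cry1 was at 0.60, Per3 at 0.46, Nr1d2 at 0.32 and Csnk1d at 0.13. Cry2 was lowest at -0.56, followed by Csnk1e and Rora, both at -0.37, Per2 at -0.33, Per1 at -0.31, Clock at -0.28 and Arntl, which encodes BMAL1, at -0.14. Nr1d1, which encodes the heme-binding receptor REV-ERBα, had 47.6 and 46.9 FPKM, a log2 ratio of -0.02 that became 0.04 with equal library totals. Npas2 was near 0 FPKM in both libraries. Each group had 1 library at 1 time, so a difference in clock phase between the cultures cannot be told from a difference in level.

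The clock-controlled transcription factors had 7 of 8 genes lower and a median of -0.23 at percentile 5.07. Bhlhe40, a clock repressor, went from 46.9 to 22.8 FPKM (log2 ratio -1.01), and Hlf, Nfil3 and Bhlhe41 were at -0.74, -0.34 and -0.28. Bhlhe41 shares 17.0% of its sequence with other loci. The mean of the members was -0.34 at percentile 1.23, so this list stands apart by its mean and not by its median.

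The S phase and mitosis list was higher, with 21 of 24 genes up in the ALA library and a median of 0.28 at percentile 99.99. The mitotic kinase Plk1 was at 0.79, the anaphase activator Cdc20 at 0.63 and the replicative helicase subunit Mcm5 at 0.47, while cyclin Ccne2 was lower at -0.63. Plk1, Cdc20 and Ccne2 each share more than 10% of their sequence with other loci. Replication-dependent histones had a median of -0.19 at percentile 18.34 over 3 measured genes, Hist1h2bc at -1.17, H2afx at -0.19 and Hist1h1c at 0.01. Their mean of -0.45 was at percentile 2.09, and Hist1h2bc and H2afx share sequence with other histone genes.

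Immediate early genes were lower in 12 of 13 cases, with a median of -0.31 at percentile 0.51. Ier3 was at -1.32, from 142 to 56.4 FPKM. Egr1 went from 25.7 to 12.3 FPKM, and Fosl1 was at -0.90 and Egr2 at -0.89. Fosl1 shares 57.2% of its exon bases with other genes. Inflammatory cytokines and NF-kB targets had 8 of 10 genes lower and a median of -0.42 at percentile 0.11. The cytokine gene Lif was at -1.38, the NF-kB inhibitor Tnfaip3 at -1.15 or 3.42 against 0.99 FPKM, and the chemokine genes Ccl2 and Ccl7 at -0.72 and -0.65. Of 3 measured macrophage and blood cell markers, Cd14 and Lyz2 were lower at -1.31 and -0.61 and Aif1 was higher at 0.32. Their median of -0.61 was at percentile 1.89, but at percentile 3.02 with a pseudocount of 0.1, and the mean was at percentile 3.77. With no filter the median was 0.17. S100a8, which is not in that list, went from 9.95 to 0.47 FPKM. Interferon response genes had a median of 0.24 at percentile 91.43, with Bst2 at 0.35, Ifit2 at 0.29 and Isg15 at -0.21.

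Metallothionein and zinc transport genes had a median of -0.44 at percentile 1.23 over 5 genes. Mt1 went from 1091 to 674 FPKM (log2 ratio -0.69) and Mt2 from 581 to 382 FPKM (-0.60), and Mtf1 was at -0.44. The zinc exporter Slc30a1 was higher at 0.75. Mt2 shares 51.5% of its sequence with other genes, of which Gm45774 shares the most. Without Mt1 or without Mt2 the median was -0.28 at percentile 9.04, without Mtf1 it was -0.36 at percentile 3.87, and the mean was -0.22 at percentile 15.41, so the list stands apart only under some settings.

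Stress and metabolic lists otherwise stayed within the range of random lists. Heat shock proteins had a median of 0.09 at percentile 94.68, with Cryab at 0.48, Hsph1 at 0.37, Hspe1 at 0.32 and Hspd1 at 0.29, and at a mean of at least 5 FPKM the median was 0.11 at percentile 97.61. Over members with under 10% shared sequence it was 0.05 at percentile 74.09. Cryab, Hspe1 and Hspd1 share more than 10% of their sequence with other loci. ATF4 amino acid response genes had a median of 0.03 at percentile 75.27: Atf3, Ddit4 and Ddit3 were at -1.36, -0.99 and -0.71, and the amino acid transporter Slc7a5 at 0.56. The ER unfolded protein response list was at -0.06 and percentile 36.70, a median that became 0.01 with equal library totals, with Xbp1 at -0.37, Dnajb9 at -0.21, Dnajc3 at 0.21 and Hyou1 at 0.20.

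Cholesterol synthesis genes had 13 of 18 members higher and a median of 0.12 at percentile 95.25. Mvd, the mevalonate diphosphate decarboxylase gene, went from 5.28 to 13.1 FPKM (log2 ratio 1.17), Nsdhl was at 0.73 and Fdft1 at 0.43, and the mean of the list was 0.16 at percentile 97.72. Fdft1 shares 28.7% of its sequence. The aryl hydrocarbon receptor list was at -0.15 and percentile 15.44, with Tiparp at -1.07, Ugt1a6a at 0.38, Nfe2l2 at -0.22 and Aldh3a1 at -0.20. Ugt1a6a shares 52.5% of its sequence with other genes, of which Ugt1a7c shares the most. The p53 targets were at 0.07 and percentile 84.26, with Bbc3 at 0.87, Ei24 at 0.60, Pmaip1 at -0.58 and Gadd45a at -0.45, of which Gadd45a overlaps another gene in 19.1% of its exon bases.

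Fibroblast matrix and contractile genes were at -0.13 and percentile 10.06, with Cnn1 at 0.92, Thbs1 at -0.46, Fn1 at -0.42, from 2367 to 1765 FPKM, and Acta2 at 0.39. Cytosolic ribosomal protein genes were at -0.12 and percentile 17.36, with Rpl3 at -0.33, Rps3 at -0.32, Rpl5 at -0.30 and Rpl10a at -0.25, of which Rpl3, Rpl5 and Rpl10a share more than 20% of their sequence with other loci. Among macrophage and blood cell markers 3 genes were measured, with a median of -0.61 at percentile 1.89. Cd14 was at -1.31 and Lyz2 at -0.61, while Aif1 was at 0.32. Lyz2 shares 22.3% of its sequence with other genes, of which Lyz1 shares the most. With no filter the median of this list was 0.17 at percentile 93.66. Of each remaining marker list 1 gene was measured: Lpl of the adipocyte list had 51.3 and 52.3 FPKM, Cdh1 of the epithelial list 1.24 and 0.94 FPKM, Epor of the erythroid list 2.501 and 1.83 FPKM, and Des of the muscle list 1.95 and 1.12 FPKM.

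**Figure D4:**
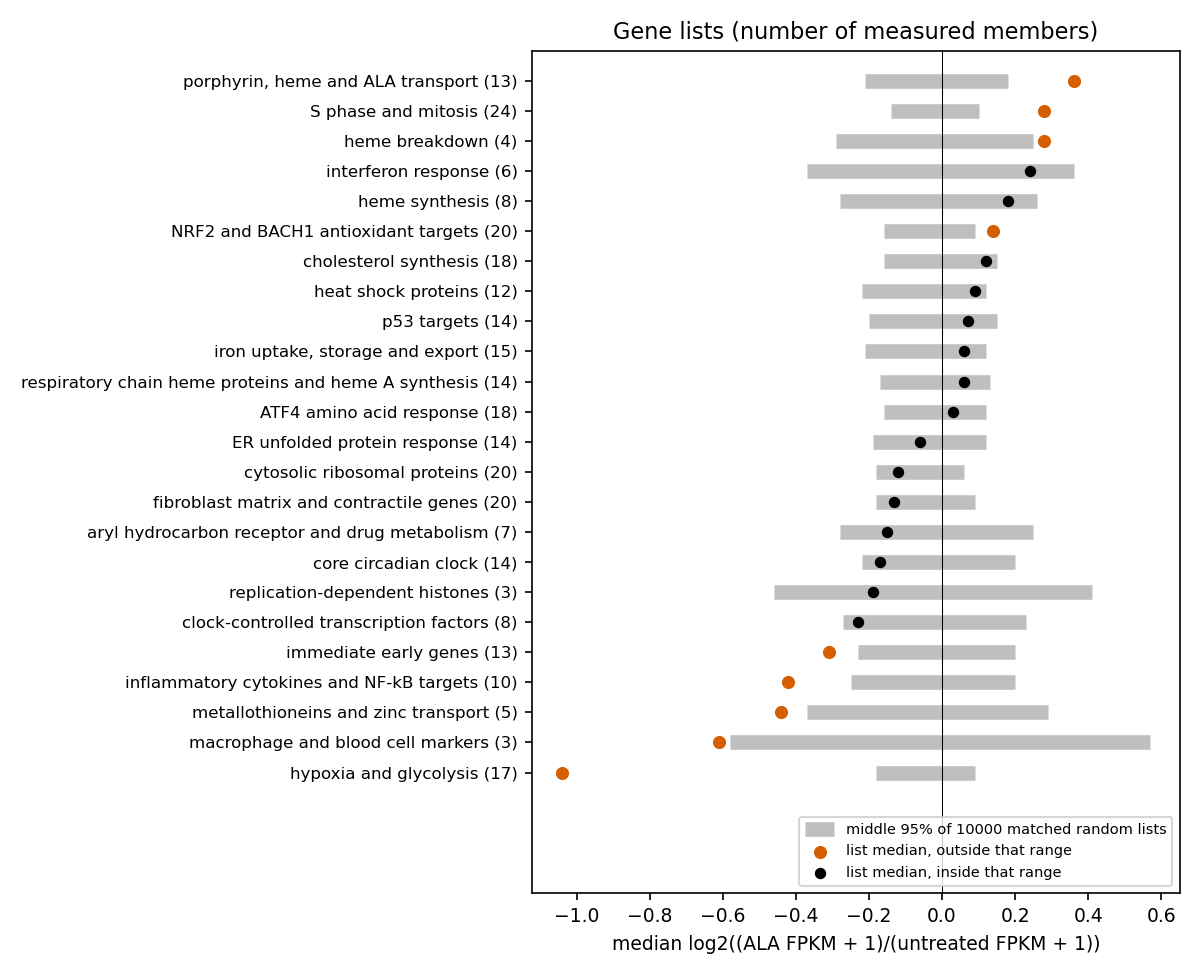
Median log2 ratio of ALA to untreated for the 24 fixed lists with at least 3 measured members (points), with the middle 95% of 10000 expression-matched random lists as grey bars and the number of measured genes in brackets. Orange points lie outside the bar of their list, and the hypoxia and glycolysis list is farthest from 0 at -1.04.

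In total 9 of 24 lists stood apart, where 5% would by chance if their genes were independent. With small-RNA names left out, the highest log2 ratios among genes with a mean of at least 5 FPKM belonged to Eif3j1 at 5.58, Rpl26 at 4.97, Rps27 at 4.70, Gm10052 at 4.29, Pet117 at 3.34 and Toporsos at 2.61. Apoo-ps, LOC100504703 and Cenpp followed at 2.18, 2.08 and 2.01. Ube2s, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, went from 193 to 711 FPKM (log2 ratio 1.87), the RNase P subunit Rpp21 from 2.23 to 10.4 FPKM (1.82), and 1600002K03Rik was at 1.81. The lowest ratios were those of Eif3j2 at -5.28, Npcd at -3.87, the calprotectin subunit S100a8 at -2.90, 5730408K05Rik at -2.70, Rps27rt at -2.44 and Mgp, matrix Gla protein, at -1.98. Below -1.6 were also 2500002B13Rik at -1.83, 2010005H15Rik at -1.75, Nhej1 at -1.74, Atp6v0c at -1.72, Gm773 at -1.69 and 2310039H08Rik at -1.68. Of these 24 genes 15 have at least 10% of their sequence shared or overlapping, or no gene model.

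For 10 pairs of genes with shared or overlapping sequence, chosen after the values were seen, the log2 ratio of the sum was nearer 0 than that of the first gene named, by differing amounts. Adding a partner with a ratio near 0 has this effect by itself. Rps27 went from 42.7 to 1133 FPKM and Rps27rt from 1547 to 285 FPKM, while their sum went from 1590 to 1418 FPKM, a log2 ratio of -0.16. Eif3j1 and Eif3j2 together had 49.8 and 54.4 FPKM (0.13), Gm10052 and Gm5643 104 and 123 FPKM (0.23), and Atp6v0c with Atp6v0c-ps2 294 and 222 FPKM (-0.40). Rpl26 with Gm15772 had 1812 and 1679 FPKM (-0.11), nearly all of it from Gm15772, and Npcd with Nptxr 34.65 and 41.7 FPKM (0.26). Toporsos with Ndufb6 was at 0.51 and Srrd with Tfip11, at 14.09 and 23.96 FPKM, at 0.73. The sums of Pet117 with Csrp2bp and of Cenpp with Ippk stayed higher with ALA, at 1.17 and 1.61. FPKM sums are not kept when reads move between genes of different length, so these sums are only a rough guide. S100a8, Mgp, Ube2s and Rpp21 share under 10% of their sequence with other annotated genes. That share counts exact matches only, so it does not exclude shared reads for these genes. Mgp went from 26.8 to 6.02 FPKM and S100a8 from 9.95 to 0.47 FPKM, or about 115 to 7 reads.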

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

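The shared-sequence filter, the GC and length correction and the plain-ratio count were chosen after the data were seen; the other alternatives were planned. Of 24 lists, 16 kept their side of the percentile limits under every alternative run, and 13 of these also their direction, hypoxia and glycolysis between -1.10 and -0.87. The other 3 were ATF4 (-0.05 by the mean), the core clock (0.00 by the mean) and the ER unfolded protein response (0.01 with equal totals). Genes at 2-fold numbered 302 higher and 389 lower with a pseudocount of 0.1, 31 and 42 with 5, and 67 and 104 at a mean of at least 5 FPKM. They numbered 102 and 144 of 8568 genes with under 10% shared sequence. At 1.5-fold there were 645 and 782, at 3-fold 49 and 42. These counts move because the scale, the threshold or the genes tested differ. Rescaling shifted log2 ratios by 0.02 (median) and 0.07 (equal totals), and equal totals gave 187 higher and 173 lower, against 163 and 220. Srrd was at 2.16 with a pseudocount of 0.1 and 1.05 with 5, since a larger pseudocount shrinks low genes. The macrophage and blood cell list no longer stood apart with a pseudocount of 0.1 (-0.66, percentile 3.02) or by the mean (-0.54, percentile 3.77), and reversed to 0.17 with no filter, which adds near-zero genes. By the mean of members, porphyrin transport was at 0.14, metallothioneins at -0.22, clock-controlled factors at -0.34, cholesterol synthesis at 0.16 and histones at -0.45; the first pair then lay within random lists and the others stood apart. Heat shock proteins stood apart at 0.11 with a mean of at least 5 FPKM, and were at 0.05 (percentile 74.09) with under 10% shared sequence. With under 10% shared sequence porphyrin transport was at 0.17 and metallothioneins at -0.28, both within random lists with fewer members. Leaving out 1 member ended the call for 7 of 13 members of porphyrin transport (0.17 without Abcb6), 3 of 5 metallothionein list members (-0.28 without Mt1) and 2 of 4 heme breakdown members (0.13 without Blvra), and for 0 members of the other 5 lists tested. Beyond these constructions the cause was not tested. Non-overlapping deposited intervals were not run, as the bounds are equal, and the macrophage list was too short to leave out members. No paired analysis was possible because each group has 1 library. Depth limits genes such as Srrd, with about 56 reads untreated.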

Other observations

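Of the tests here, library scaling of the hypoxia list, the culture difference, read sharing among extreme ratios and the tests of Srrd were chosen after the result was seen, and 3 further gene lists were drawn up after the data were seen but without looking up their values. Besides the fixed lists, growth factor and MAPK response genes were lower in the ALA library in all 13 measured cases, with a median log2 ratio of -0.37. Of these genes, 4 were at least 1.5-fold lower, 9 were lower by less than that, and 0 reached 2-fold. Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, went from 37.1 to 18.8 FPKM, Phlda1 from 34.4 to 18.6 FPKM, the growth factor Btc from 15.3 to 8.02 FPKM, and the ERK phosphatase Dusp5 from 10.2 to 5.41 FPKM. Phlda1 and Dusp5 share more than 10% of their sequence with other loci.

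Among 6811 genes with a mean of at least 5 FPKM and under 10% shared sequence, chosen after the data were seen, the highest log2 ratios after Ube2s, Rpp21 and 1600002K03Rik were Nudt14 at 1.64, adenosine deaminase Ada at 1.62, the tubulin chaperone Tbce at 1.46, B9d1 at 1.38, Hddc2 at 1.34, Gm1673 at 1.30, Cmtm7 at 1.27, Pgp at 1.27 and Coq10b at 1.25. On the low side, Maff, a small MAF transcription factor, was at -1.58, Spn-ps at -1.54, Pcbd2 at -1.47, Cdk20 at -1.46, the ER oxidase Ero1l at -1.42, from 225 to 83.2 FPKM, and the iron-sulfur protein Cisd3 at -1.41. These followed S100a8, Mgp, 2500002B13Rik, Nhej1, Gm773 and 2310039H08Rik.

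The uniformly lower hypoxia and glycolysis list was the clearest pattern. A single scaling factor moves all genes alike, and the median of all measured genes was -0.019. After subtracting GC and length bins the list median was -1.09, and over members with little exactly shared sequence -1.10. These values argue against scaling, GC content, length and exactly shared sequence, each as the whole cause. Sequence shared with mismatches was not covered. A candidate explanation is lower HIF-dependent transcription in the ALA library: in a further list of HIF targets, 16 of 16 measured genes were lower, 13 of them at least 1.5-fold, with a median of -0.76 at percentile 0.00, among them Ak4, Gys1, Plod2 and P4ha1. With 1 library per group, a difference between the cultures other than ALA, such as density or oxygen, cannot be told apart from ALA.

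On the log2 scale with 1 FPKM added, ratios of 8-fold or more were found for 8 genes with a mean of at least 5 FPKM. Simulations of counting noise gave 0, which argues against counting error for genes with a gene model. Gm10052 and Eif3j2, which are among the 8, have no gene model and were not simulated. Reads divided differently between near-identical or overlapping genes may account for most of the 8 ratios. Of the 8 genes, 7 have shared or overlapping sequence or no gene model, against 20.8% of the other genes. The odds ratio was 19.1, computed with 0.5 added to each of the 4 counts. By the plain FPKM ratio there were 10 such genes, 8 of them with shared or overlapping sequence or no gene model. The exceptions were Snora23, a small nucleolar RNA gene listed at 0 untreated and at 10.3 FPKM with ALA, and S100a8. The sum of Pet117 and its overlapping partner Csrp2bp was still at 1.17, which does not settle that gene, because FPKM sums are not kept when reads move between genes of different length. Whether the assignment of reads in fact differed between the libraries, and why, was not tested directly.

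The higher Srrd value is not counting error, since the lower bound of its log2 counting interval was 1.5. Reads taken from Tfip11 would lower Tfip11, which was at 0.23. A rise of Tfip11 itself could hide such a loss, so this value does not exclude it. If reads covered Tfip11 evenly, more of them would add at least as many FPKM to Tfip11 as to Srrd. Tfip11 added 2.21 FPKM and Srrd 7.65 FPKM, so the gain of Tfip11 was 28.9% of that of Srrd. The overlap lies at the 3' ends and gene values do not show coverage, so uneven coverage is not excluded. Longer Tfip11 transcripts that cover more of Srrd were not tested, because gene values do not separate exons, and an effect of ALA on Srrd remains a hypothesis from 1 library per group.

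Both remaining hypotheses came from gene names near the ends of the ranking. Higher expression of coenzyme Q synthesis and respiratory chain assembly genes as a class was not borne out: their list of 26 genes had a median of 0.03 at percentile 73.27, with Sco2 at -1.05 and Pet100 at -1.01. The growth factor and MAPK list was at percentile 0.04, which is consistent with weaker growth factor signalling in the ALA library, and the immediate early genes point the same way. The S phase and mitosis list goes against it, with 21 of 24 genes higher at percentile 99.99. A difference in density or serum between the 2 cultures could give the same pattern and was not tested.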
